A study of Mus musculus with 33 samples.

How the data were processed

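RNA-seq libraries of 33 samples were used, in 4 deposited tables: 6 libraries of HC11 cells treated with trichostatin A (TSA) or DMSO, 4 of HC11 cells with a guide RNA against Trps1 or a scrambled guide, 12 of mammary organoids and 11 of mammary tumors. Per the labels' protocols, RNA was taken with the AllPrep kit, had an integrity number above 8, and was made into libraries with a TruSeq kit. The protocols do not say whether the kit kept the strand, so values of genes that overlap a gene on the other strand, and of close paralogs, are uncertain. Per the submitters' processing notes, reads were aligned to GRCm38 with TopHat and counted per gene with HTSeq; the versions and the annotation are not given in the sources used here. Nothing in the labels says that replicates of a group are separate cultures, so p-values of the cell lines and organoids measure the spread between these samples, which may be technical.

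Each deposited table holds, per the file headers, log2 values of normalized counts, made by the authors. In every library the values were those of log2(normalized count + 1), where the normalized count is a whole number of reads times 1 factor per library. This was checked by dividing by the smallest step of each library: 100% of the values fell within 0.01 reads, or a share of 1e-05 of the value, of a whole number. The factors differ between tables, since each table was normalized on its own, so levels are tested only within a table and a level in 1 table is not measured against a level in another. Reads per library, summed from the recovered reads, ran from 17809076 to 25614664 in the TSA table, from 21374525 to 38773073 in the guide RNA table, from 14858175 to 30341897 in the organoids and from 18320414 to 24225027 in the tumors. Reads were not marked with molecular identifiers, so intervals and floors below cover counting error only.

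In each table, 14 symbols that a spreadsheet had turned into dates were left out. The guide RNA and organoid tables had 1 row each without a symbol, which held at most 5.16e-06% and 1.31e-05% of a library and was left out. In the organoid table, 8 of 12 columns have a header that 2 columns share, so their replicates are called a and b in column order. Symbols were matched to GENCODE M21 (GRCm38) for coordinates: 99.4% of the tested symbols matched in the TSA table, 95.1% in the guide RNA table, 95.0% in the organoids and 99.4% in the tumors.

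The deposited log2 values were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), without recounting. A gene was kept when its normalized count, with 1 added, was at least 10 in at least as many libraries as the smallest group had. Organoids were fitted with all 6 groups in 1 model. Tumors of a mouse were averaged before the genotype comparison, and averaged within a subgroup before the subgroup comparisons, so that mice were the replicates. A gene was called changed at an adjusted p (Benjamini-Hochberg over the kept genes) under 0.05. Fold changes are differences of mean log2(normalized count + 1), which understates the change of genes with few reads. Where a group had no reads of a gene, the fold was computed against 3 counts over the group and is given as a lower bound; where a group had 1 to 3 counts, the ratio is given with its 95% counting interval. In 1 library, 3 counts equal 2.26 to 3.36 normalized counts (TSA), 1.55 to 2.76 (guides), 2.03 to 4.51 (organoids) or 2.66 to 3.37 (tumors).

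The comparisons, the tests, 33 lists of genes and the rule for naming genes were fixed before the data were examined. Trps1 and Cdh1 are named in every comparison. In a comparison with calls, genes were named from the 8 rising and the 8 falling genes with the largest log2 fold change among those with an adjusted p under 0.05, groups that did not overlap, a mean in the higher group above the median of the kept genes, and a symbol that is not a clone name, predicted gene, pseudogene or mitochondrial. For the difference between days, the differences between libraries had to not overlap. Groups of 2 libraries do not overlap by chance in 33.3% of genes, and groups of 3 in 10.0%. From each list that passed or is described, up to 4 members with the smallest p were eligible. In a comparison without calls, the 5 genes with the smallest p are named. Genes chosen in another way are marked as such. Some genes that the rule would name are not reported here.

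Lists with at least 5 kept members were tested with camera, which asks whether members changed more than other genes, with a preset correlation of 0.01, adjusted over the lists of a comparison. Beside it stand camera with an estimated correlation, adjusted likewise, and fry, which asks whether members move 1 way on balance. Of 484 tests, 193 passed with the preset correlation, 4 of them held with the estimated correlation, and fry passed 254, of which 133 were among the 193. "Adjusted over the list alone" gives the members that pass when only the list's p-values are adjusted. Lists of markers of other cell types were written for macrophages and myeloid cells, T and NK cells, B and plasma cells, fibroblasts, endothelium, adipocytes and skeletal muscle; 12 of the 22 fibroblast genes, 1 of the 22 endothelial genes, 1 of the 21 adipocyte genes, 1 of the 20 B and plasma cell genes and 0 of the other lists' genes also stand in another list. HC11, an epithelial line, passed the filter for 12 fibroblast, 7 endothelial, 6 adipocyte and 9 muscle genes.

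Fold changes of pairs of comparisons without shared libraries were compared across genes by Pearson and Spearman correlation (5 pairs, and 1 more added after the data were seen), which describe genes and not independent replicates. The tables of differential expression that the authors deposited give log2 fold changes and adjusted p-values, per the file headers. No source used here names their tool. They were used only to be set beside the limma results.

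Alternatives were no filter, a shift of each library to a common median, quantile normalization, an offset of 10 inside the log, no variance trend, leaving out each library or mouse, only the libraries of the groups compared, tumors as replicates, mouse as a random block (limma's duplicateCorrelation with statmod 1.5.0), and a replicate block where the columns carry numbers. limma-voom on the recovered reads (each tumor as a replicate), sgTrps1 without the genes of chromosomes 10 and 16, and correlations with each library left out were added after the data were seen. Where leaving out a library left a group with 1 library, that library was assumed to vary like those of the other groups.

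The tests were checked on simulated counts drawn with the means and library sizes of the real genes and a spread that followed a trend with expression, without a spread of its own per gene, which makes the recovery optimistic. Among genes changed 1.5-fold, 2-fold and 4-fold, 88.1%, 100% and 100% were called in the design of TSA against DMSO (12854 genes), 91.0%, 97.0% and 100% in that of the guides (12476 genes), 74.6%, 92.5% and 98.5% in that of organoids at day 14 (15527 genes), 7.46%, 35.8% and 89.4% in the genotype design of the tumors (15423 genes) and 7.46%, 47.8% and 89.4% in that of subgroup 1 (15840 genes). In this order, 17 of 12624, 7 of 12246, 10 of 15297, 8 of 15194 and 4 of 15610 unchanged genes were called. Of 50 random lists, 0, 0, 0, 0 and 1 had a camera p under 0.05, with correlation untested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and random draws used seed 1.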

Results

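Gene expression was measured by RNA-seq in 33 samples of mouse mammary origin. HC11, a mouse mammary epithelial cell line, was treated for 24 h with 300 nM trichostatin A (TSA), an inhibitor of histone deacetylases, or with its solvent DMSO, with 3 libraries each. HC11 cells that carried a guide RNA against Trps1 (sgTrps1) or a scrambled guide (sgScr) gave 2 libraries each, with 1 guide per arm. Mammary organoids, in which the floxed alleles were recombined with a virus that expresses Cre, were taken at day 14 and day 28 of culture in Matrigel. They had 3 genotypes with 2 libraries per genotype and day: Cdh1F/F;Trps1+/+ (called Trps1+/+ below), then Cdh1F/F;Trps1F/F, and last Cdh1+/F;Trps1F/F. Mammary tumors came from mice that express Cre in the mammary gland: 8 tumors of 6 mice were Cdh1F/F;Trps1F/F (called Trps1F/F below), and 3 tumors of 3 mice were Cdh1F/F;Trps1+/+. The labels put the 8 tumors into subgroups: subgroup 1 has 4 tumors of 3 mice, subgroup 2 has 2 tumors of 2 mice and subgroup 3 has 2 tumors of 2 mice. Mouse 18LCO025 gave 3 tumors, which fall in subgroups 1 and 3. How the subgroups were defined is not given in the sources used here; if expression defined them, subgroup comparisons are not independent evidence. Libraries held 17809076 to 25614664 reads in the TSA experiment, 21374525 to 38773073 in the guide RNA experiment, 14858175 to 30341897 in the organoids and 18320414 to 24225027 in the tumors. Libraries of a group differed by more than counting error, with a chi-square per degree of freedom of 1.56 to 7.77 for TSA and DMSO, 3.84 to 10.97 for the guides, 8.32 to 19.5 for the organoids and 76.4 to 531 for the tumors.

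Trps1 (chromosome 15, 50654752 to 50890463, GRCm38) encodes a zinc finger repressor of the GATA family, and Cdh1 (chromosome 8, 106603351 to 106670246) encodes the adhesion protein E-cadherin. A floxed allele can still give reads from exons outside the deleted part, and a guide RNA leaves a small insertion or deletion, so read counts of the whole gene check these designs only in part. Trps1 stood at 13.97 ± 0.0448 (SD, n = 3) on the log2 scale in DMSO and at 10.93 ± 0.0400 (SD, n = 3) in TSA. It did not differ between sgScr (13.84 ± 0.0676, SD, n = 2) and sgTrps1 (13.88 ± 0.0427, SD, n = 2, log2 fold change 0.04, limma adjusted p = 0.676), so Trps1 mRNA gives no check of the guide. In organoids at day 14 it stood at 13.55 in Trps1+/+, 9.74 in Cdh1+/F Trps1F/F and 11.33 in Cdh1F/F Trps1F/F, and at day 28 at 13.79, 9.75 and 11.14. Both genotypes with floxed Trps1 were below Trps1+/+ on both days, as the labels have it. In tumors, Trps1 stood at 11.09 ± 1.03 (SD, n = 6 mice) in Cdh1F/F Trps1F/F and 12.35 ± 0.782 (SD, n = 3 mice) in Trps1+/+, a difference that did not pass (log2 fold change -1.26, limma adjusted p = 0.802). Cdh1 stood at 13.08 to 13.88 in all organoid groups, although all carry floxed Cdh1, so its whole-gene counts do not show the recombination. The tables were normalized separately, so levels are not comparable between experiments.

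**Figure D1:**
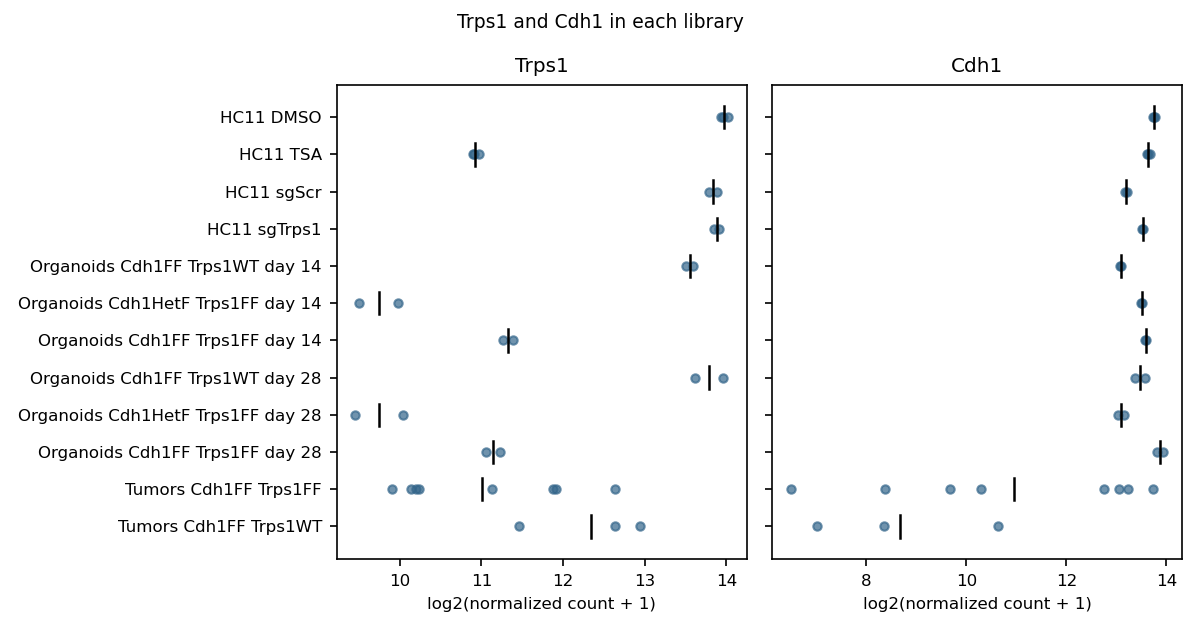
Levels of Trps1 and Cdh1 in every group, as log2(normalized count + 1) on the horizontal axis; points are libraries and black bars are group means. Trps1 stands lower in TSA (10.93) than in DMSO (13.97), does not separate sgTrps1 (13.88) from sgScr (13.84), and is lower in both organoid genotypes with floxed Trps1 than in the third at each day.

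TSA was compared with DMSO to find the genes of HC11 cells that respond when histone deacetylases, with which repressors of the GATA family can act, are inhibited. Trps1 fell by 3.05 on the log2 scale (SE 0.0383, limma adjusted p = 6.85e-14), in all 3 TSA libraries. Cdh1 was lower by a small step (log2 fold change -0.11, adjusted p = 0.0149). This call was lost without DMSO replicate 2 (-0.10, adjusted p = 0.0584), TSA replicate 1 (-0.10, 0.0582) or TSA replicate 2 (-0.10, 0.0616) and with libraries shifted to a common median (-0.07, 0.0890). Among the largest rises were Vgf (log2 fold change 10.88, SE 0.269, chromosome 5, 137026392 to 137033351), the precursor of neuroendocrine peptides, and Atp1b2 (10.33, chromosome 11, 69599736 to 69605942), a sodium pump subunit of glia. Disp2, a neuronal relative of a Hedgehog release protein, rose 1004-fold (95% counting interval 278 to 8294, chromosome 2, 118779719 to 118811293), and the antiviral gene Rsad2 by 7.66. Mmp14, which encodes a membrane-bound matrix protease (-5.83, chromosome 14, 54431612 to 54445364), the water channel gene Aqp5 (-4.85), the cyclin D1 gene Ccnd1 (-4.67, chromosome 7, 144929931 to 144939925) and the inflammatory caspase gene Casp1 (-4.58) were among the largest falls.

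Cell division genes fell together in TSA. Of 32 S phase genes, 29 fell and 1 rose (29 and 1 over the list alone, median log2 fold change -1.08, camera adjusted p = 5.59e-08). They include the ribonucleotide reductase gene Rrm1 (-2.00) and the replication helicase genes Mcm3 (-2.26) and Mcm6 (-2.08). All 31 genes of G2 and mitosis fell (31 over the list alone, median -1.22, camera adjusted p = 7.08e-10), with the mitotic kinase gene Cdk1 at -2.01 and the transcription factor gene Foxm1 at -1.65. Against these, 20 of 27 p53 target genes rose and 7 fell (20 and 7 over the list alone, median 0.81, camera adjusted p = 0.0207). The cell cycle inhibitor gene Cdkn1a (3.18) and the stress gene Ddit4 (2.76) were among those that rose. Genes known to respond to deacetylase inhibitors rose in 18 of 20 cases and fell in 2 (18 and 2 over the list alone, median 2.10, camera adjusted p = 6.51e-05). The chaperone gene Clu rose by 6.84 and the metallothionein genes Mt2 by 5.45 and Mt1 by 3.45. Neuronal genes, which corepressors keep silent outside neurons, rose in 12 of 13 cases with 0 falling (12 over the list alone, median 2.28, camera adjusted p = 0.00180). With an estimated correlation between genes these 5 lists did not pass (adjusted p 0.309 to 0.336).

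Antigen presentation genes rose in 12 of 14 cases and fell in 2 in TSA (12 and 2 over the list alone, median 1.92, camera adjusted p = 0.0147), with the class I genes H2-D1 at 3.63 and H2-K1 at 2.29. Cholesterol synthesis genes rose in 15 of 23 cases and fell in 5 (15 and 5 over the list alone, median 0.46, camera adjusted p = 0.0479). The enzyme genes Mvk (1.98) and Dhcr7 (1.55) were among those that rose. The 6 measured genes of the adipocyte list all rose (6 over the list alone, median 2.47, camera adjusted p = 0.0147). Examples are the acyl-CoA synthetase gene Acsl1 (2.27), the lipase genes Pnpla2 (1.54) and Lipe (3.11) and the glucose carrier gene Slc2a4 (4.49). Actomyosin genes fell in 17 of 27 cases and rose in 7 (17 and 7 over the list alone, median -0.51, camera adjusted p = 0.0384). In total 11110 of 13044 genes changed (5688 up, 5422 down, 51.2% up, and 48.7% after quantile normalization), 2806 up and 2123 down by 2-fold or more, so a single gene or list changing carries little weight in this comparison. The 4 lists of this paragraph did not pass with an estimated correlation either (adjusted p 0.336 to 0.624).

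sgTrps1 was compared with sgScr to ask how HC11 cells with a guide against Trps1 differ. Trps1 mRNA did not change, as given above, and Cdh1 rose by 0.33 (limma adjusted p = 0.000884, both sgTrps1 libraries above both sgScr libraries). Ppic, a cyclophilin gene, had no reads in sgScr and was at least 665-fold higher in sgTrps1. HC11 in DMSO had 4216 reads of it, so sgScr is the odd arm. The serpin gene Serpinb6b (log2 fold change 7.68, chromosome 13, 32965209 to 32979067), the steroid dehydrogenase gene Akr1c18 (6.61) and the growth factor gene Bmp7 (5.43, chromosome 2, 172868012 to 172940321) were among the largest rises. Among the largest falls were Pogk (-8.40, chromosome 1, 166384622 to 166409863), a gene derived from a transposon, and Trim44 (-8.28). The axon guidance gene Sema3a (-6.42, chromosome 5, 13125414 to 13602565) and the complement gene C3 (-4.89) were among them too. Of 12562 genes, 8424 changed (4351 up, 4073 down, 51.7% up, and 46.9% after a shift to a common median), 869 up and 872 down by 2-fold or more. With 1 guide per arm and 2 libraries each, a difference between the cell populations that the guide did not make cannot be separated from an effect of Trps1.

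Interferon response genes rose strongly in sgTrps1: 25 of 29 rose and 3 fell (25 and 3 over the list alone, median log2 fold change 2.65, camera adjusted p = 7.20e-09). Among them were the interferon signalling factor gene Irf9 (2.40), the brake of that pathway Usp18 (5.42), Ifi27 (2.65) and Xaf1 (3.21). Cytokine and chemokine genes of the NF-kB pathway fell in 17 of 18 cases with 0 rising (17 over the list alone, median -1.53, camera adjusted p = 8.21e-08). These include the prostaglandin synthase gene Ptgs2 (-2.87), the cytokine gene Lif (-2.58) and the neutrophil chemokine genes Cxcl1 (-3.22) and Cxcl5 (-4.41). Of 32 S phase genes 29 rose and 2 fell (29 and 2 over the list alone, median 0.53, camera adjusted p = 1.02e-07). Of 32 genes of G2 and mitosis 31 rose and 0 fell (31 over the list alone, median 0.86, camera adjusted p = 5.99e-11). Examples of both are Chaf1b (1.56) and Mcm4 (1.08), both on chromosome 16, Kif11 (1.44) and the proliferation marker gene Mki67 (1.12). Oxidative phosphorylation genes rose in 27 of 30 cases with 0 falling (27 over the list alone, median 0.50, camera adjusted p = 8.21e-08), with Atp5o (chromosome 16) at 1.05 and Cox7a2 at 1.03. Squamous keratinization genes rose in 8 of 13 cases and fell in 1 (8 and 1 over the list alone, median 0.47, camera adjusted p = 0.0224). The desmosome gene Dsg1a (3.21) and the keratin gene Krt6a (2.30) led them. Luminal epithelial genes did not pass as a list (13 rose and 8 fell of 26, median 0.23, camera adjusted p = 0.332). None of the 6 lists that passed did so with an estimated correlation (adjusted p = 0.625 for each).

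Genes of chromosomes 10 and 16 stood higher as a whole in sgTrps1. The median log2 fold change was 0.42 over 574 genes of chromosome 10, of which 80.3% were positive, and 0.32 over 363 genes of chromosome 16, of which 72.7% were positive. The other 18 chromosomes had medians from -0.16 to 0.09 (SD 0.0785). On these 2 chromosomes 592 genes rose and 125 fell of 937 tested, against 3759 and 3948 of 11625 elsewhere. Without the genes of chromosomes 10 and 16, 7712 genes changed (3763 up, 3949 down). Without their members there, a test chosen after the data were seen, the 6 lists passed by camera with the preset correlation but not with an estimated one (adjusted p = 0.583 for each). The medians were then 0.49 over 27 S phase genes, 0.85 over 31 of G2 and mitosis, 2.40 over 25 of the interferon response, -1.66 over 17 NF-kB genes and 0.48 over 28 of oxidative phosphorylation, and no squamous gene lay there.

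**Figure D2:**
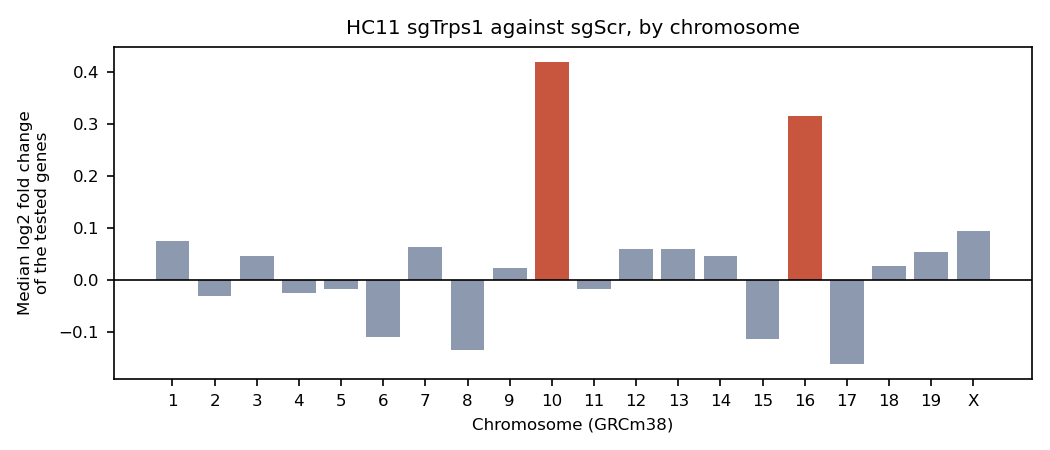
Median log2 fold change (vertical axis, sgTrps1 minus sgScr) of the tested genes of each chromosome (horizontal axis), with bars that start at 0. Chromosome 10 (0.42) and chromosome 16 (0.32) stand above the other 18, which run from -0.16 to 0.09.

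Cdh1F/F Trps1F/F organoids were compared with Trps1+/+ organoids at day 14 to ask what floxed Trps1 adds where Cdh1 is floxed in both. Trps1 fell by 2.22 on the log2 scale (SE 0.182, limma adjusted p = 1.96e-06), and Cdh1 rose by 0.51 (adjusted p = 0.000631). Among the largest rises were Clca2 (log2 fold change 6.79, chromosome 3, 145070263 to 145099443) and Clca1 (6.27, chromosome 3, 145003817 to 145032776), neighbouring genes of secreted chloride channel regulators, the scavenger receptor gene Scara3 (4.72, chromosome 14, 65919394 to 65953935). The chaperone gene Clu (3.995, chromosome 14, 65968483 to 65981547), a neighbour of Scara3, rose too. The alarm cytokine gene Il33 (-3.63, chromosome 19, 29925114 to 29960718), the collagen gene Col3a1 (-3.27, chromosome 1, 45311538 to 45349706), the collagen crosslinking enzyme gene Lox (-2.79) and the collagenase gene Mmp13 (-2.78) were among the largest falls. Of 15873 genes, 5153 changed (2308 up, 2845 down, 546 up and 1496 down by 2-fold or more, 44.8% up, and 50.3% after quantile normalization), and 3289 without Cdh1F/F Trps1F/F day 14 replicate 1.

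Luminal epithelial genes rose at day 14 in 27 of 30 cases and fell in 1 (27 and 2 over the list alone, median 0.68, camera adjusted p = 4.07e-14). The tight junction genes Cldn4 (3.08) and Marveld2 (0.90) and the adhesion gene Epcam (1.00) led this list. Mesenchymal genes fell in 18 of 26 cases with 0 rising (21 down over the list alone, median -0.92, camera adjusted p = 9.82e-09), among them Prrx1 (-1.85) and Sparc (-1.09). Matrix genes fell in 20 of 30 cases and rose in 4 (20 and 4 over the list alone, median -1.19, camera adjusted p = 1.19e-07). The laminin gene Lama4 stood at -1.47, Bgn at -1.75 and Thbs1, against the list, at 2.16. The markers of stromal cells moved with them. All 21 fibroblast genes fell (21 over the list alone, median -1.54, camera adjusted p = 7.88e-12), with Col1a2 at -2.57. Of 21 skeletal muscle genes 20 fell and 0 rose (20 over the list alone, median -1.74, camera adjusted p = 7.88e-12), with Ttn at -1.98. Macrophage and myeloid genes fell in 16 of 21 cases with 0 rising (18 over the list alone, median -1.33, camera adjusted p = 3.92e-08), with Mpeg1 at -1.90. Endothelial genes fell in 6 of 20 cases and rose in 2 (11 and 3 over the list alone, median -0.94, camera adjusted p = 0.0375), with Erg at -4.13 and Flt4 at 2.17. These 7 lists did not pass with an estimated correlation (adjusted p 0.242 to 0.353).

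Interferon response genes fell at day 14 in 25 of 32 cases and rose in 1 (27 and 2 over the list alone, median -0.77, camera adjusted p = 1.47e-08). Ifit2 (-1.84) and Isg15 (-1.03) are examples, and the direction was opposite to that in HC11 sgTrps1. Antigen presentation genes fell in 7 of 20 cases with 0 rising (7 over the list alone, median -0.40, camera adjusted p = 0.00347), among them Nlrc5 (-1.06) and B2m (-0.76). Genes of the unfolded protein response, which refolds secretory proteins, fell in 20 of 28 cases and rose in 1 (21 and 1 over the list alone, median -0.60, camera adjusted p = 1.88e-08), with Hspa5 at -1.12 and Pdia4 at -0.92. Smaller rises were found for 4 lists. S phase genes rose in 14 of 32 cases with 0 falling (18 over the list alone, median 0.39, camera adjusted p = 3.78e-06), as Chaf1b (0.95). Genes of G2 and mitosis rose in 5 of 32 cases with 0 falling (1 over the list alone, median 0.31, camera adjusted p = 0.00334), as Ect2 (0.65). Of 23 cholesterol synthesis genes 11 rose and 1 fell (14 and 2 over the list alone, median 0.28, camera adjusted p = 0.000936). Of 32 subunits of deacetylase complexes 11 rose and 1 fell (12 and 1 over the list alone, median 0.16, camera adjusted p = 0.00181), with Hdac3 at 0.73. With an estimated correlation none of these 7 lists passed (adjusted p 0.153 to 0.734).

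At day 28 the same genotypes were compared to ask whether the differences last in longer culture. Trps1 fell by 2.65 (SE 0.182, limma adjusted p = 3.14e-07) and Cdh1 rose by 0.40 (adjusted p = 0.00237). Clca2 (log2 fold change 9.68), Clca1 (7.50), Scara3 (5.44) and the transcription factor gene Mecom (4.36, chromosome 3, 29951296 to 30548008) were among the largest rises. Cilp, a cartilage matrix gene (-4.66, chromosome 9, 65265180 to 65280605), the collagen genes Col2a1 (-3.85, chromosome 15, 97975602 to 98004695) and Col1a2 (-3.73, chromosome 6, 4504814 to 4541544) and the acute phase gene Saa2 (-3.60) were among the largest falls. Of the tested genes, 6862 changed (3155 up, 3707 down, 817 up and 1844 down by 2-fold or more).

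All 32 genes of G2 and mitosis rose at day 28 (32 over the list alone, median 2.13, camera adjusted p = 1.86e-23), such as Ccna2 (2.36) and Prc1 (2.31). Of 32 S phase genes 31 rose and 0 fell (32 over the list alone, median 1.17, camera adjusted p = 1.04e-16), such as Rrm2 (1.99). Cholesterol synthesis genes rose in 23 of 23 cases (23 over the list alone, median 1.05, camera adjusted p = 1.35e-16), with the sterol enzyme genes Cyp51 at 1.60, Nsdhl at 1.42 and Fdft1 at 1.30. Luminal epithelial genes rose in 20 of 30 cases and fell in 1 (20 and 1 over the list alone, median 0.34, camera adjusted p = 8.99e-07), with Cldn4 at 2.18 and Aldh1a3 at 1.63. The unfolded protein response, which was lower at day 14, was higher, with 15 of 28 genes up and 4 down (16 and 4 over the list alone, median 0.28, camera adjusted p = 0.0128). Interferon response genes stayed lower, with 26 of 32 down and 0 up (26 over the list alone, median -1.01, camera adjusted p = 7.49e-10), as Oas2 (-2.39) and Ifit2 (-2.08). Antigen presentation genes fell in 10 of 20 cases with 0 rising (10 over the list alone, median -0.63, camera adjusted p = 0.000287), as H2-Q7 (-1.45). An estimated correlation left none of these 7 lists past the threshold (adjusted p 0.0860 to 0.345).

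Mesenchymal genes fell at day 28 in 20 of 26 cases and rose in 2 (21 and 3 over the list alone, median -1.28, camera adjusted p = 8.99e-07). Lox stood at -2.77, Fn1 at -1.69 and Vim, against the list, at 1.15. Matrix genes fell in 19 of 30 cases and rose in 2 (19 and 2 over the list alone, median -1.34, camera adjusted p = 1.08e-06), as Lum (-3.12) and Bgn (-2.28). Again the stromal markers moved with them. Of 21 fibroblast genes 19 fell and 0 rose (19 over the list alone, median -1.82, camera adjusted p = 4.01e-11), and all 21 skeletal muscle genes fell (21 over the list alone, median -2.44, camera adjusted p = 3.49e-12). Macrophage and myeloid genes fell in 15 of 21 cases and rose in 1 (15 and 1 over the list alone, median -1.11, camera adjusted p = 0.000182). Adipocyte genes fell in 13 of 19 with 0 rising (13 over the list alone, median -1.37, or -1.33 with members without reads at their bound, camera adjusted p = 4.88e-05). An estimated correlation left none of these 6 lists past it (adjusted p 0.276 to 0.377).

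Cdh1+/F Trps1F/F organoids were compared with Trps1+/+ organoids, a contrast in which both genes differ, to complete the genotype series. Trps1 fell by 3.81 at day 14 (limma adjusted p = 1.10e-08) and by 4.04 at day 28 (adjusted p = 2.73e-09). Cdh1 was higher at day 14 (log2 fold change 0.43, adjusted p = 0.00191) and lower at day 28 (-0.38, adjusted p = 0.00264). Of 15873 genes, 5760 changed at day 14 (2995 up, 2765 down, 1388 up and 789 down by 2-fold or more, 45.6% up after quantile normalization), and 3709 without Trps1+/+ day 14 replicate a. At day 28, 8462 changed (4550 up, 3912 down, 2421 up and 1147 down by 2-fold or more). The share of calls that rose at day 28 was 53.8%, and 41.8% after quantile normalization. At day 14 Dpysl4, a neuronal growth cone gene, rose 427-fold (95% counting interval 146 to 2076, chromosome 7, 139086001 to 139102704), the corneal matrix gene Kera by 7.08 (chromosome 10, 97606879 to 97613692) and Clca2 by 5.36. The secreted protein gene Coch (-7.37) and the carbonic anhydrase gene Car4 (-5.40) fell. At day 28 Clca2 (8.01), the complement gene C7 (7.51, chromosome 15, 4988762 to 5063740) and Lum (6.31, chromosome 10, 97565128 to 97572703) rose. The nucleoside carrier gene Slc28a3 (-6.50, chromosome 13, 58545399 to 58610877), the interferon target Ifi44 (-4.72) and the binding protein gene Igfbp3 (-4.72, chromosome 11, 7206086 to 7213923) fell.

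Stromal markers and matrix genes rose in Cdh1+/F Trps1F/F. At day 14, 18 of 21 fibroblast genes rose and 0 fell (18 over the list alone, median 1.85, camera adjusted p = 6.40e-12), and 24 of 30 matrix genes rose and 2 fell (24 and 3 over the list alone, median 1.67, camera adjusted p = 3.07e-13). Macrophage and myeloid genes rose in 17 of 21 cases and fell in 1 (17 and 1 over the list alone, median 1.39, camera adjusted p = 6.76e-06). Mesenchymal genes rose in 12 of 26 cases and fell in 3 (13 and 3 over the list alone, median 0.45, camera adjusted p = 0.00173). Skeletal muscle genes rose in 10 of 21 cases with 0 falling (11 over the list alone, median 0.72, camera adjusted p = 0.000503). At day 28, 20 of 21 fibroblast genes rose and 0 fell (21 over the list alone, median 3.0, camera adjusted p = 7.97e-13), and 28 of 30 matrix genes rose and 1 fell (29 and 1 over the list alone, median 2.54, camera adjusted p = 1.38e-13). Mesenchymal genes rose in 19 of 26 cases and fell in 2 (23 and 2 over the list alone, median 1.92, camera adjusted p = 1.18e-07). Skeletal muscle genes rose in 20 of 21 cases with 0 falling (21 over the list alone, median 3.09, camera adjusted p = 1.32e-11), and adipocyte genes rose in 16 of 19 and fell in 1 (16 and 1 over the list alone, median 1.68, camera adjusted p = 1.07e-05). With an estimated correlation no list of this paragraph passed at either day (adjusted p 0.212 to 0.524).

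Interferon response genes fell in Cdh1+/F Trps1F/F as well. At day 14, 29 of 32 fell and 0 rose (30 over the list alone, median -1.22, camera adjusted p = 1.69e-16), and at day 28, 28 fell and 1 rose (28 and 1 over the list alone, median -1.40, camera adjusted p = 2.43e-13), as Rtp4 (-2.23 and -3.02). Genes of the unfolded protein response fell at day 14 in 20 of 28 cases and rose in 1 (20 and 3 over the list alone, median -0.73, camera adjusted p = 5.98e-10), with Hspa5 at -1.43. Cholesterol synthesis genes rose at day 14 in 21 of 23 cases with 0 falling (21 over the list alone, median 0.64, camera adjusted p = 1.09e-09), with Nsdhl at 1.13. Genes of G2 and mitosis fell in 28 of 32 cases at day 14 with 0 rising (30 over the list alone, median -0.78, camera adjusted p = 1.22e-09), as Ccna2 (-1.18). At day 28, 15 of them fell and 1 rose (15 and 1 over the list alone, median -0.40, camera adjusted p = 0.00243). S phase genes fell in 13 of 32 cases at day 14 with 0 rising (14 over the list alone, median -0.31, camera adjusted p = 0.000102) and in 17 at day 28 with 1 rising (18 and 2 over the list alone, median -0.41, camera adjusted p = 0.00144). Basal genes fell at day 14 in 13 of 23 cases and rose in 5 (13 and 5 over the list alone, median -0.90, camera adjusted p = 0.000776). Among these, Col17a1 (-3.02), Trp63 (-2.72) and Krt5 (-2.24) fell while the contractile gene Acta2 rose (2.23). Luminal genes fell at day 28 in 21 of 30 cases and rose in 1 (21 and 2 over the list alone, median -0.68, camera adjusted p = 3.23e-07), as Krt7 (-2.55) and Krt8 (-1.31). Squamous genes fell at day 28 in 14 of 21 cases and rose in 2 (15 and 2 over the list alone, median -1.42, camera adjusted p = 0.000115), as Dsg3 (-3.13). Here too no list of either day passed with an estimated correlation (adjusted p 0.114 to 0.583).

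Cdh1F/F Trps1F/F organoids were compared with Cdh1+/F Trps1F/F organoids because both carry floxed Trps1 and differ in 1 allele of Cdh1. Trps1 was higher in Cdh1F/F Trps1F/F on both days (log2 fold change 1.58, limma adjusted p = 1.51e-05, and 1.40, adjusted p = 2.38e-05). Recombination was not measured and may differ, which could give this. Cdh1 did not differ at day 14 (0.08, adjusted p = 0.494) and was higher in Cdh1F/F Trps1F/F at day 28 (0.78, adjusted p = 5.34e-06). Luminal genes were higher too, so epithelial share is not separated from this. At day 14, 6443 genes changed (3017 up, 3426 down, 809 up and 2203 down by 2-fold or more, 46.8% up, and 57.7% after quantile normalization). At day 28, 9003 changed (4397 up, 4606 down, 1286 up and 2944 down by 2-fold or more, 48.8% up, and 61.8% after quantile normalization). The desmosome gene Dsg3 was higher in Cdh1F/F Trps1F/F on both days (4.28 and 4.47, chromosome 18, 20510274 to 20547459), as were Krt17 at day 14 (3.93) and the antimicrobial peptide gene Defb1 at day 28 (7.42, chromosome 8, 21776599 to 21795185). Kera had no reads in Cdh1F/F Trps1F/F at day 14 and was at least 440-fold lower, and Srpx stood at -9.14 (chromosome X, 10037977 to 10117709). At day 28 the microfibril gene Mfap4 was 1216-fold lower (95% counting interval 416 to 5898, chromosome 11, 61485431 to 61488900) and Lum stood at -9.43.

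All 21 fibroblast genes were lower in Cdh1F/F Trps1F/F than in Cdh1+/F Trps1F/F on both days (medians -3.17 and -5.45, camera adjusted p = 3.60e-18 and 2.54e-15). Of 30 matrix genes 25 and 28 were lower, with 1 and 2 higher (medians -2.83 and -3.48, camera adjusted p = 6.69e-18 and 7.23e-15), such as Col3a1 at day 14 (-7.55). Skeletal muscle genes were lower in 20 and 21 of 21 cases (medians -2.55 and -5.51, camera adjusted p = 2.38e-13 and 5.47e-15). Macrophage and myeloid genes were lower in 19 and 15 of 21, with 0 and 2 higher (medians -2.73 and -2.15, camera adjusted p = 2.66e-11 and 0.000205). Of 26 mesenchymal genes 20 and 23 were lower, with 4 and 2 higher (medians -1.75 and -2.73, camera adjusted p = 4.42e-09 and 2.03e-10). Adipocyte genes were lower in 9 and 18 of 19 cases, with 1 and 0 higher (medians -0.82 and -3.41, camera adjusted p = 0.00780 and 7.50e-09). With members without reads at their bound, these medians were -0.79 and -3.35. Endothelial genes were lower in 14 and 12 of 20 cases, with 4 and 2 higher (medians -1.74 and -1.47, the latter -1.15 with such members at their bound, camera adjusted p = 0.00832 and 0.0336). Higher were luminal genes, in 23 and 29 of 30 cases, with 2 and 1 lower (medians 0.52 and 1.01, camera adjusted p = 6.84e-07 and 4.82e-13). S phase genes were higher in 28 and 32 of 32 cases (medians 0.69 and 1.43, camera adjusted p = 8.53e-11 and 1.24e-14), and genes of G2 and mitosis in 30 and 32 of 32 (medians 1.12 and 2.57, camera adjusted p = 6.00e-12 and 2.19e-17). Interferon response genes were higher in 18 and 21 of 32 cases, with 2 and 3 lower (medians 0.48 and 0.71, camera adjusted p = 3.04e-05 and 0.000634). Cholesterol synthesis genes were lower at day 14 (13 of 23, with 2 higher, median -0.36, camera adjusted p = 0.00112) and higher at day 28 (22 of 23, with 1 lower, median 0.84, camera adjusted p = 1.11e-08). Adjusted over the list alone the counts were the same, except at day 14 for muscle (21 lower), mesenchymal (21 lower), luminal (24 higher), S phase (30 higher), G2 and mitosis (31 higher), interferon (20 higher) and cholesterol genes (14 lower) and at day 28 for macrophage and myeloid genes (16 lower). None of these lists passed with an estimated correlation (adjusted p 0.177 to 0.315).

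**Figure D3:**
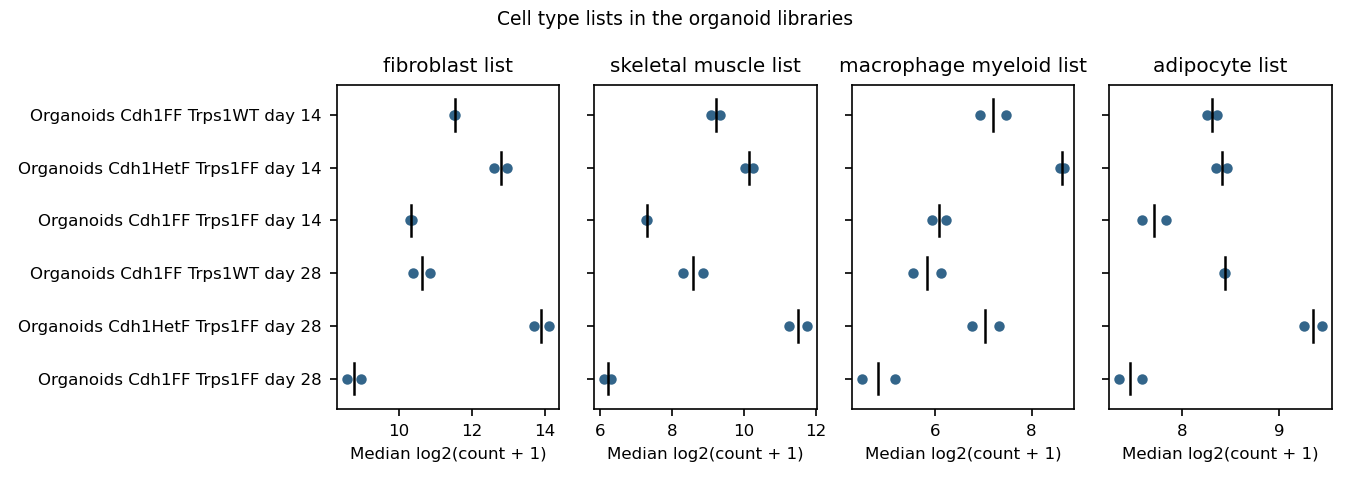
Median log2(normalized count + 1) of the genes of the fibroblast, skeletal muscle, macrophage and myeloid, and adipocyte lists (horizontal axis) in each organoid group (vertical axis). Points are libraries and bars are means of 2 libraries. The fibroblast list stands at 12.79 in Cdh1+/F Trps1F/F, 11.53 in Trps1+/+ and 10.33 in Cdh1F/F Trps1F/F at day 14, and at 13.90, 10.62 and 8.77 at day 28.

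Day 28 was compared with day 14 within a genotype to find the genes that change with time in culture. In Trps1+/+, Trps1 did not change (log2 fold change 0.24, limma adjusted p = 0.368) and Cdh1 rose (0.39, adjusted p = 0.00534), a call lost without Trps1+/+ day 28 replicate a (0.29, adjusted p = 0.0598). Of 15873 genes, 4110 changed (1768 up, 2342 down, 325 up and 938 down by 2-fold or more, 43.0% up, and 52.7% after quantile normalization), and 2311 without day 14 replicate a. The collagen gene Col2a1 (3.51) and the mast cell protease gene Mcpt2 (2.73) rose, and Coch (-6.83), the axon guidance gene Slit1 (-5.81) and the matrix protease gene Ctsk (-4.03, chromosome 3, 95499256 to 95509362) fell. Genes of the unfolded protein response fell in 24 of 28 cases with 0 rising (24 over the list alone, median -0.97, camera adjusted p = 4.70e-20, and 0.0158 with an estimated correlation), as Hspa5 (-2.04), Hsp90b1 (-1.94) and Pdia6 (-1.75). Milk protein genes fell in 7 of 20 cases and rose in 1 (8 and 1 over the list alone, median -0.54, camera adjusted p = 0.000789), as Csn3 (-3.52) and Ltf (-2.51). Stromal markers fell too. Macrophage and myeloid genes fell in 18 of 21 cases with 0 rising (20 over the list alone, median -1.44, camera adjusted p = 1.32e-09), and endothelial genes in 10 of 20 with 1 rising (12 and 1 over the list alone, median -1.42, camera adjusted p = 0.000342). Fibroblast genes fell in 14 of 21 cases with 2 rising (15 and 2 over the list alone, median -1.31, camera adjusted p = 7.29e-06), and muscle genes in 9 of 21 with 0 rising (14 over the list alone, median -0.66, camera adjusted p = 0.000342). The estimated correlation gave these lists adjusted p of 0.374 to 0.494.

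In Cdh1F/F Trps1F/F, Trps1 did not change with time (log2 fold change -0.18, limma adjusted p = 0.458) and Cdh1 rose (0.29, adjusted p = 0.0212). The latter call was lost without Cdh1F/F Trps1F/F day 14 replicate 1 (0.30, adjusted p = 0.0933), day 14 replicate 2 (0.28, adjusted p = 0.0980) or day 28 replicate 2 (0.23, adjusted p = 0.149). In this genotype 5621 genes changed (2348 up, 3273 down, 416 up and 1025 down by 2-fold or more), and 2818, 3424 and 2978 without the same 3 libraries. All 32 genes of G2 and mitosis rose (32 over the list alone, median 1.72, camera adjusted p = 3.14e-26), as Ccna2 (1.90) and Prc1 (1.81). Of 32 S phase genes 24 rose and 0 fell (25 over the list alone, median 0.61, camera adjusted p = 9.06e-11). Of 23 cholesterol synthesis genes 21 rose and 0 fell (22 over the list alone, median 1.06, camera adjusted p = 7.22e-21, and 0.0463 with an estimated correlation), as Cyp51 (1.76) and Nsdhl (1.43). Fibroblast genes fell in 16 of 21 cases and rose in 2 (16 and 3 over the list alone, median -1.55, camera adjusted p = 3.98e-07), as Lum (-4.40). Matrix genes fell in 23 of 30 cases and rose in 4 (23 and 4 over the list alone, median -0.86, camera adjusted p = 3.97e-07), as Lama2 (-3.27). Muscle genes fell in 17 of 21 cases with 0 rising (17 over the list alone, median -1.33, camera adjusted p = 3.26e-07), and macrophage and myeloid genes in 16 of 21 with 0 rising (17 down and 1 up over the list alone, median -1.25, camera adjusted p = 4.63e-06). Interferon response genes fell in 20 of 32 cases with 0 rising (20 over the list alone, median -0.61, camera adjusted p = 3.98e-07), as Oas2 (-2.62). With an estimated correlation the other lists of this paragraph had an adjusted p of 0.341.

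The interaction of day and genotype tests whether the effect of floxed Trps1 in Cdh1F/F organoids differs between the days. For Trps1 (log2 difference -0.42, limma adjusted p = 0.273) and Cdh1 (-0.10, adjusted p = 0.589) it did not pass. Of 15873 genes, 2848 passed (1307 up, 1541 down). There were 1060 without Trps1+/+ day 14 replicate a, 1803 without its day 28 replicate b, 1016 and 1662 without Cdh1F/F Trps1F/F day 14 replicates 1 and 2, 1807 without its day 28 replicate 2, and 1665 without a variance trend. The effect moved up with time for all 32 genes of G2 and mitosis (32 over the list alone, median 1.82, camera adjusted p = 2.11e-28, and 0.400 with an estimated correlation), as Ccna2 (2.39) and Top2a (2.07). It did so for 19 of 32 S phase genes with 0 down (24 over the list alone, median 0.77, camera adjusted p = 2.24e-12, and 0.400). The same was found for 17 of 23 cholesterol synthesis genes with 0 down (18 over the list alone, median 0.85, camera adjusted p = 1.58e-16, and 0.0423), as Cyp51 (1.48) and Idi1 (1.63). For the unfolded protein response, 19 of 28 genes moved up and 0 down (19 over the list alone, median 0.81, camera adjusted p = 5.77e-13, and 0.0423), as Hsp90b1 (1.70) and Hspa5 (1.57).

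Fold changes were compared across genes, to ask whether sgTrps1 resembles TSA, and whether HC11, organoids and tumors share guide and floxed Trps1 effects. Genes are not independent replicates, so no p-value is given for a correlation. sgTrps1 against TSA gave a Pearson correlation of 0.0822 over 11088 genes. Of 6503 genes called in both, 53.1% had the same sign (1727 up in both against 1597 by chance, 1725 down in both against 1623). Against Cdh1F/F Trps1F/F over Trps1+/+ organoids, sgTrps1 gave 0.0726 at day 14, where the Spearman correlation had the other sign (-0.0178), and 0.147 at day 28 (12104 genes each), with 48.7% of 2548 and 59.9% of 3606 shared calls of the same sign. The organoid effect at day 14 and at day 28 correlated at 0.699 over 15873 genes, with 92.4% of 3289 shared calls of the same sign (1223 up in both against 459 by chance, 1816 down in both against 664). The organoid effect at day 28 and the tumor genotype effect correlated at 0.314 over 13531 genes. As sets (camera p unadjusted here), genes up or down in sgTrps1 did not pass in TSA, nor those of TSA in sgTrps1 (0.0959 to 0.883). Genes up in sgTrps1 were higher in organoids at day 28 (median 0.09, camera p = 9.77e-05, and 0.00300 with an estimated correlation), while those down in it did not pass (0.879). Shared calls exceeded chance in both directions (1220 up in both against 965, 939 down in both against 740). At day 14 genes down in sgTrps1 were higher, the other direction (median 0.05, camera p = 0.0220, and 0.0764 with an estimated correlation). Yet their overlaps with genes up (768 against 642 by chance) and down in the organoids (590 against 510) both exceeded chance. Genes that fell in organoids at day 28 were lower in Trps1F/F tumors as a set (median -0.23, camera p = 3.20e-06, and 0.0416 with an estimated correlation), while those that rose did not pass (0.0748). Fibroblast genes were lower in both, so cell composition could give this and the 0.314.

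Trps1F/F tumors of 6 mice were compared with Trps1+/+ tumors of 3 mice to ask how tumors with floxed Trps1 differ. Trps1 stood at -1.26 (SE 0.602, limma adjusted p = 0.802) and Cdh1 at 1.81 (SE 1.56, adjusted p = 0.808), neither past the threshold. limma called 0 of 15095 genes, with 791 at an unadjusted p under 0.05 and a smallest adjusted p of 0.336, and limma-voom on recovered reads, with each tumor as a replicate, called 0. The 5 genes with the smallest p, none past the threshold, were Oaz2, a regulator of polyamines (-1.26, adjusted p = 0.336, chromosome 9, 65668001 to 65690300), the cannabinoid receptor gene Cnr1 (-3.70, adjusted p = 0.401), and 3 genes with an adjusted p of 0.802. These were the collagen receptor gene Itga1 (-1.58), the matrix protease gene Adamts4 (-1.21) and the collagen gene Col18a1 (-1.29). Without mouse 18LCO027, Cnr1 alone passed (-4.03, adjusted p = 0.0275).

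No member of any list passed in the tumors by genotype, while lists differed from other genes by camera. Of the 32 lists tested there, fry passed 0. Lower were matrix genes (median of 30 genes -1.246, 0 up and 2 down over the list alone, camera adjusted p = 1.24e-13) and mesenchymal genes (26, -1.18, 0 and 2 over the list alone, 7.02e-12). So were fibroblast genes (21, -1.60, 6.38e-11), endothelial genes (22, -1.24, 3.80e-10), genes of G2 and mitosis (31, -0.54, 4.63e-06), macrophage and myeloid genes (23, -0.58, 0.000216) and adipocyte genes (19, -1.85, 0.00269). Higher were luminal epithelial genes (30, 1.89, 0.00317), milk protein genes (17, 1.42, 0.0212) and glycolysis genes (31, 0.42, 0.00684). In the 5 lists after the mesenchymal one and in the 3 higher lists, 0 members passed over the list alone. None of these lists passed with an estimated correlation (adjusted p 0.297 to 0.827), and the tumors differ within the genotype, so these values describe 9 mice.

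Tumors of subgroup 1 were compared with Trps1+/+ tumors, 3 mice each, as the labels divide the Trps1F/F tumors. Trps1 stood at -1.70 and did not pass (SE 0.582, limma adjusted p = 0.0837), and without mouse 17LCO103 it passed (-2.31, adjusted p = 0.0272). Cdh1 was higher (log2 fold change 4.46, SE 1.09, adjusted p = 0.0289), at 13.13 ± 0.336 (SD) against 8.67 ± 1.83 (SD), in all 3 mice. That call was lost without mouse 17LCO103 (4.65, adjusted p = 0.0658), 18LCO003 (4.40, adjusted p = 0.0840), 18LCO025 (4.33, adjusted p = 0.0505), 18LCO114 (4.30, adjusted p = 0.0940) or 18LCO128 (3.63, adjusted p = 0.0953). Of 15735 genes, 2458 changed (1401 up, 1057 down, 1109 up and 707 down by 2-fold or more), and 1503, 1208, 1603, 1132 and 1151 without the same 5 mice in that order. Gabrp, a receptor subunit gene of secretory epithelium (10.35, chromosome 11, 33550781 to 33578959), the calcium channel gene Trpv6 (9.24) and the milk protein gene Ltf (9.16, chromosome 9, 111019271 to 111042767) were among the largest rises. The retinoic acid binding protein gene Crabp2 (-5.37), the motility gene S100a4 (-5.01, chromosome 3, 90603771 to 90606045) and Cnr1 (-4.86) were among the largest falls.

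Luminal epithelial genes rose in subgroup 1 in 21 of 30 cases with 0 falling (26 over the list alone, median 6.01, camera adjusted p = 9.70e-13), as the transcription factor genes Ehf (8.81) and Ovol1 (5.39) and the protease inhibitor gene Spint1 (6.63). Milk protein genes rose in 7 of 17 cases with 0 falling (10 over the list alone, median 4.27, camera adjusted p = 8.03e-06), as Cidea (8.28) and Mfge8 (2.08). Basal genes rose in 5 of 23 cases and fell in 1 (6 and 1 over the list alone, median 0.65, camera adjusted p = 0.0424), as Krt17 (6.86) and Id4 (5.16), and squamous genes rose in 4 of 16 with 0 falling (8 over the list alone, median 1.90, camera adjusted p = 0.0112). Mesenchymal genes fell in 12 of 26 cases with 0 rising (16 over the list alone, median -1.52, camera adjusted p = 1.65e-09). Genes of G2 and mitosis fell in 5 of 31 cases (20 over the list alone, median -1.27, camera adjusted p = 8.62e-09) and S phase genes in 3 of 32 (3 over the list alone, median -0.65, camera adjusted p = 2.14e-05). Stromal markers moved with the mesenchymal genes. Macrophage and myeloid genes fell in 8 of 23 cases and rose in 1 (17 and 1 over the list alone, median -1.22, camera adjusted p = 8.03e-06), as Mrc1 (-3.59). Endothelial genes fell in 3 of 22 cases with 0 rising (5 over the list alone, median -1.21, camera adjusted p = 3.15e-05), as Cdh5 (-1.72), and matrix genes in 5 of 30 with 2 rising (8 and 2 over the list alone, median -1.12, camera adjusted p = 0.000899), as Nid1 (-2.18). Fibroblast genes fell in 2 of 21 cases with 0 rising (0 over the list alone, median -1.12, camera adjusted p = 0.0101). With an estimated correlation none of these lists passed (adjusted p 0.825 to 0.910). Median levels of the luminal list were 10.73 to 11.37 in the 4 tumors of subgroup 1, 2.72 to 4.32 in the other Trps1F/F tumors, and 8.18, 4.21 and 3.498 in the Trps1+/+ tumors of mice 18LCO046, 18LCO114 and 18LCO128.

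Subgroup 2 (2 mice) and subgroup 3 (2 mice) were each compared with the 3 Trps1+/+ mice. Trps1 stood at -1.66 (limma adjusted p = 0.334) and -0.08 (adjusted p = 0.995), and Cdh1 at 0.35 (adjusted p = 0.928) and -0.28 (adjusted p = 0.986). In subgroup 2 limma called 0 genes, with 2097 at an unadjusted p under 0.05 and limma-voom on each tumor at 0. There, 3 were called without mouse 17LCO102, 16 without 18LCO027 and 1 without 18LCO046. The 5 genes with the smallest p, none past the threshold, were the noncoding Wincr1 (lower by a ratio with a 95% counting interval of 35.1 to 1057), the choline carrier gene Slc5a7 (6.58) and the cofactor gene Vgll3 (-3.11), each with an adjusted p of 0.0666, and Galnt17 (-5.18) and Ephb2 (-2.53), each at 0.106. Slc5a7 passed with an offset of 10 inside the log (adjusted p = 0.00241) and Ephb2 without mouse 18LCO027 (-3.01, adjusted p = 0.0462). In its lists no member passed, but lists were lower by camera, each with an adjusted p of 0.673 with an estimated correlation. These were skeletal muscle genes (median -5.53 over 22 genes, 0 over the list alone, camera adjusted p = 1.38e-07), adipocyte genes (20, -3.69, 8 down over the list alone, 2.58e-07) and fibroblast genes (21, -2.74, 11 down over the list alone, 4.00e-10). So were endothelial genes (22, -1.88, 16 down and 1 up over the list alone, 4.50e-11) and matrix genes (30, -1.65, 13 down over the list alone, 6.94e-10). In subgroup 3 limma called 1 gene, the developmental factor gene Zic2 (chromosome 14, 122475435 to 122479852), which had no reads in the Trps1+/+ tumors and was at least 107-fold higher (adjusted p = 0.0283), with 953 genes at an unadjusted p under 0.05 and 1 by limma-voom on each tumor. Zic2 was not past the threshold without mouse 18LCO025 (adjusted p = 0.0975), 18LCO046 (0.0914), 18LCO114 (0.255) or 18LCO128 (0.167) or with the tumors of these groups alone (0.586), and 29 genes were called without 18LCO052. Interferon response genes were higher in subgroup 3 (median 1.04 over 32 genes, 0 passing also over the list alone, camera adjusted p = 4.42e-05, and 0.765 with an estimated correlation). They were lower in subgroup 2 (median -1.04, camera adjusted p = 3.32e-05, and 0.673), where again 0 passed over the list alone.

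The authors' deposited table gave 11268 genes with an adjusted p under 0.05 for TSA (6046 up, 5222 down), 7178 for sgTrps1 (3637 up and 3541 down in sgTrps1), 4756 for Cdh1F/F Trps1F/F organoids at day 14 (2137 up, 2619 down) and 5151 at day 28 (2461 up, 2690 down). Their fold changes correlated with those above across genes at 0.991, 0.986, 0.972 and 0.986, and all 10505, 7007, 4437 and 5080 genes called in both had the same sign. For the tumor subgroups the authors' deposited table called more genes, with 4158 in subgroup 1 (2230 up, 1928 down), 738 in subgroup 2 (197 up, 541 down), and 54 up and 49 down in subgroup 3. Of these 2409, 0 and 1 were also called here, with correlations of 0.938, 0.923 and 0.849. In subgroup 1 it gave Trps1 as lower (-1.70, adjusted p = 0.0122) and Cdh1 as higher (3.82, adjusted p = 0.000122).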

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

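The tests of this part followed rules set beforehand. In 6 Cdh1F/F Trps1F/F mice, 40 values of named genes and list medians were tested for a mouse that stands apart from the others, which chance gives about 1 time in 20, and 2 were found. Col18a1 stood at 13.94 in mouse 18LCO027 against 12.93 to 13.23 in the others. The median of the germline list stood at 3.03 in mouse 18LCO003 against 4.21 to 4.91.

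The genotype effect of Cdh1F/F Trps1F/F over Trps1+/+ organoids was tested for a difference between the days by the interaction. Of 26 genes named for a single day or by design, 12 passed. The 10 others below (Car6, Ccna2, Csn3, Kif23, Kif4, Nuf2, Kif11, Cpm, Cdsn and Wisp2) were chosen because they passed it. At day 28 minus day 14 it was higher for Clca2 (2.89), Car6 (2.65), Ccna2 (2.39), Csn3 (2.37), Kif23 (2.36), Kif4 (2.27), Nuf2 (2.24), Kif11 (2.21), Mmp13 (1.15), Mecom (1.14) and Scara3 (0.71). It was lower for Cpm (-2.69), Cdsn (-2.50), Cilp (-2.32), Col2a1 (-2.25), Wisp2 (-2.05), Rnase1 (-1.97), Smoc1 (-1.76), Apod (-1.36), Col1a2 (-1.16), Lipk (-1.02) and Clu (-0.75). Csn3 stood at -1.59 at day 14 and 0.78 at day 28, and Cpm at 2.11 and -0.58.

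Of these, 6 lost the call without 1 library, given here as the adjusted p without it. In Trps1+/+, leaving out day 14 replicate a gave 0.113 for Car6, 0.0907 for Cilp, 0.0501 for Clu and 0.0953 for Col1a2. Day 14 replicate b gave 0.0648 for Car6, 0.0525 for Cilp, 0.0608 for Scara3 and 0.122 for Lipk, day 28 replicate a 0.0566 for Scara3 and 0.0833 for Lipk, and day 28 replicate b 0.103 for Car6, 0.0841 for Cilp, 0.0621 for Col1a2 and 0.0559 for Lipk. In Cdh1F/F Trps1F/F, day 14 replicate 1 gave 0.136 for Car6, 0.0722 for Cilp, 0.0787 for Col1a2, 0.0819 for Scara3 and 0.0971 for Lipk. Day 14 replicate 2 gave 0.0541 for Car6, 0.0834 for Cilp, 0.0559 for Col1a2, 0.0617 for Scara3 and 0.119 for Lipk, day 28 replicate 1 0.0560 for Scara3 and 0.113 for Lipk, and day 28 replicate 2 0.0827 for Car6.

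By camera, 10 of 33 lists differed between the days. With an estimated correlation only cholesterol synthesis and the unfolded protein response did (adjusted p = 0.0423 each, the others 0.400 to 0.836), and 5 of the 10 passed with fry. The median effect was higher at day 28 for genes of G2 and mitosis (1.82), cholesterol synthesis (0.85), the unfolded protein response (0.81), S phase (0.77), milk proteins (0.53) and glycolysis (0.18), and lower for adipocyte (-0.56), skeletal muscle (-0.43), interferon response (-0.32) and luminal epithelial genes (-0.25). The luminal and interferon effects kept their sign at both days (0.68 and 0.34, and -0.77 and -1.01), while that of the unfolded protein response turned (-0.60 and 0.28).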

How the results depend on the processing

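limma-voom, sgTrps1 without the genes of chromosomes 10 and 16, and correlations with a library left out were chosen after the results were seen. Counts of called genes stayed within 1.5 times under the alternatives, except those given here. The interaction gave 1665 without a variance trend, and subgroup 2 gave 1 with an offset of 10 inside the log. Subgroup 3 gave 2 with quantile normalization, an offset of 10 inside the log or no variance trend, 0 with only the tumors of the 2 groups, and 3 with each tumor as its own replicate or mouse as a random block.

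Leaving out 1 library gave 3289 (Cdh1F/F Trps1F/F day 14 replicate 1) to 4257 calls for Cdh1F/F Trps1F/F over Trps1+/+ at day 14. It gave 3709 (Trps1+/+ day 14 replicate a) to 5021 for Cdh1+/F Trps1F/F over Trps1+/+ at day 14, and 2311 (day 14 replicate a) to 2998 for day 28 over day 14 in Trps1+/+. Within Cdh1F/F Trps1F/F it gave 2818 (day 14 replicate 1), 3424 (day 14 replicate 2) and 2978 (day 28 replicate 2) to 5853. The interaction ran from 1016 to 3517, with 1016 and 1662 without Cdh1F/F Trps1F/F day 14 replicates 1 and 2, 1807 without its day 28 replicate 2, 1060 without Trps1+/+ day 14 replicate a and 1803 without its day 28 replicate b. Leaving out 1 mouse gave 0 to 1 (18LCO027) for tumors by genotype, and 1132 (18LCO114), 1151 (18LCO128), 1208 (18LCO003), 1503 (17LCO103) and 1603 (18LCO025) to 1997 for subgroup 1. It gave 0 to 16 for subgroup 2 (16 without 18LCO027, 3 without 17LCO102, 1 without 18LCO046) and 0 (18LCO025, 18LCO114 or 18LCO128) to 29 (18LCO052) for subgroup 3.

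Cdh1 in TSA was not past the threshold after the shift to a common median (-0.0669). Leaving out a library gave -0.12 to -0.0974, not past it without DMSO replicate 2 (-0.0980), TSA replicate 1 (-0.10) or TSA replicate 2 (-0.0974). For day 28 over day 14, Cdh1 ran from 0.293 (not past it, without day 28 replicate a) to 0.49 in Trps1+/+. It ran from 0.226 to 0.35 in Cdh1F/F Trps1F/F, not past it without day 14 replicate 1 (0.296), day 14 replicate 2 (0.282) or day 28 replicate 2 (0.226). In subgroup 1, Trps1 ran from -2.31 (past it, without 17LCO103) to -1.32. Cdh1 ran from 3.63 (without 18LCO128) to 5.44 (without 18LCO046), not past it without 17LCO103 (4.65), 18LCO003 (4.40), 18LCO025 (4.33), 18LCO114 (4.30) or 18LCO128 (3.63).

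The correlation of sgTrps1 with TSA was 0.0687 without a filter and 0.0642 to 0.0957 with a library left out. With organoids at day 14 it was 0.0451 without a filter, -0.0178 by Spearman, and 0.0593 to 0.0833, and at day 28 0.0848 without a filter and 0.119 to 0.164. Organoids at day 14 against day 28 gave 0.552 without a filter, 0.765 over genes called in at least 1 of the 2, 0.550 by Spearman, and 0.632 to 0.725 with a library left out. Organoids at day 28 against tumors gave 0.235, 0.376, 0.227 in that order, and 0.261 to 0.358.

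Of 193 list calls, 4 held with camera and an estimated correlation. Quantile normalization moved the median of all genes by -0.125 for Cdh1+/F Trps1F/F over Trps1+/+ and by 0.135 for Cdh1F/F Trps1F/F over Cdh1+/F Trps1F/F at day 28, and the shift to a common median moved it by 0.127 for subgroup 2. Under either, the median of 0 called lists changed sign. Of 10151 values of named genes with a library or mouse left out, 577 were no longer called, 42 became called and 0 turned sign. Without a variance trend these were 71, 7 and 0 of 2032, and with limma-voom 20, 12 and 0 of 1505. The replicate block gave 10986 calls for TSA, 8260 for sgTrps1 and 6336 for day 28 over day 14 in Cdh1F/F Trps1F/F. The numbers do not pair the samples (correlations of residuals with the same number -0.0840, -0.00338 and -0.0631 in TSA, -0.194 in sgTrps1 and -0.0315 in those organoids). No paired analysis was possible for the other organoid comparisons, because each shared header gives both columns of a group the same number.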

Other observations

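The tests of explanations in this part were chosen only after the result was seen, except the test for a few strongly changed genes, the splits of samples, and the test for the cell cycle genes alone. Of 30 subunits of deacetylase complexes, 19 fell and 9 rose in TSA (19 and 9 adjusted over the list alone; median -0.66; camera adjusted p = 0.0793), such as Mta3 (-3.00) and Chd3 (-2.49), and Gata3 fell (-1.78) while Gata2 rose (3.42). In Cdh1F/F Trps1F/F organoids at day 28, the GATA cofactor gene Zfpm1 rose (1.10) and 6 of 8 GATA family genes fell (6 adjusted over the list alone; median -1.35; camera adjusted p = 0.0584), Trps1 among them. Hormone sensing genes rose and fell alike (5 and 4 of 15; camera adjusted p = 0.465), with the growth factor gene Areg (2.73) up. YAP targets went both ways (8 up, 9 down of 28; camera adjusted p = 0.526), with Ankrd1 (3.36) up and Ctgf (-1.88) down. T and NK cell genes were lower in tumors by genotype (median -0.69; camera adjusted p = 0.0224, and 0.827 with an estimated correlation), as were B and plasma cell genes (-0.86; 0.0159, and 0.725).

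A candidate explanation of the higher genes of chromosomes 10 and 16 in sgTrps1 is extra copies of both in these cells: with each chromosome in 5 equal parts, the lowest of the 10 medians was 0.248, against 0.0948 at most for another chromosome. That 80.3% and 72.7% of their genes were positive argues against a few strongly changed genes, on which the lower median without genes changed by 2-fold or more (0.256) decides nothing. The tables argue against an effect of floxed Trps1 or deacetylase inhibition seen elsewhere (0 of 3 other comparisons show it). A gene dose of interferon response genes on these chromosomes alone is argued against by the median of 2.40 over the members elsewhere. Of genes chosen after their values were seen, the receptor genes Ifnar1 (0.59), Ifnar2 (2.07) and Ifngr2 (0.59) lie on chromosome 16 and Ifngr1 (0.59) on chromosome 10. Copy number was not measured, and whether the guide has a part in it stays open.

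In organoids, stromal markers were lower in Cdh1F/F Trps1F/F and higher in Cdh1+/F Trps1F/F. More fibroblasts in the latter could give this. That 100% of fibroblast markers were lower in the former on both days restates the pattern. Less epithelium alone would raise all other types alike. Extremes of 4 list medians stood 2.18 apart (SE 0.499, over genes only). Both causes stay open. Stromal cells that keep Trps1 would put more Trps1 reads in Cdh1+/F Trps1F/F, but Trps1 was higher in Cdh1F/F Trps1F/F (by 1.40 at day 28, the smaller difference). This stays open, since recombination may differ between the genotypes and was not measured. A mesenchymal change of the epithelium itself cannot be told apart: mesenchymal genes outside the fibroblast list had a median of -2.50, and the same cells would express them.

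In subgroup 1, the highest adipocyte, fibroblast or endothelial median was -0.70. Normal gland with stroma stays open, as Trps1+/+ tumors express these genes too. Normal epithelium alone cannot be told apart from epithelial tumor cells, since the lowest of the luminal, basal and milk medians was 0.65 and both would raise them. Reads of Cdh1 exons outside the deleted part may add to its level, and 23 luminal genes had a larger fold change than Cdh1, which leaves this open. A biological difference between subgroups is untested, as their definition is not known.

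Splits of the 6 TSA and DMSO libraries, 10 in all, are too few for a share under 0.05; the real split, 1 of 10 with as many calls, gave 11110 and the highest other 0. The 10 splits for subgroup 1 are likewise too few; the real split, 1 of 10, gave 2458 and the highest other 3. For tumors by genotype, the real split called 0 by limma (791 at an unadjusted p under 0.05, limma-voom on each tumor 0), so that all 84 of 84 splits call at least as many by construction and the count decides nothing. The highest other called 2267, which points to a structure of the samples, though no test of one was made.

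In HC11, 33 genes had a mean normalized count of 50 or more in 1 guide arm and at most 5 reads in the other. Of 21 such genes of sgScr, 18 were in the DMSO table and 16 had a mean of 10 or more there, and of 12 of sgTrps1, all were in it and 5 had. Fold changes of TSA and of Cdh1F/F Trps1F/F organoids at day 28 correlated at -0.191 over 11705 genes, and at -0.182 without the 63 cell cycle genes, and 64.7% of 4368 genes called in both went in opposite directions.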
